A study of Mus musculus with 10 samples.

How the data were processed

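Gene expression in the left ventricle was measured on 10 Affymetrix Mouse Genome arrays, 3 of wild-type males, 3 of HCM males, 2 of wild-type females and 2 of HCM females, each array holding labelled RNA from a pool of 2 or 3 animals aged 2 months. The deposited values are log2 signals per probe set, which the authors made by robust multi-array averaging (RMA) in Affymetrix Expression Console, whose version is not given in the sources used here. The labels do not say whether all 10 arrays were normalized together. The values ran from 2.57 to 14.7 with medians of 3.86 to 4.03 per array, as log2 signals do. No probe-level file was used.

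Of 45101 probe sets, 64 controls were set aside. The array annotation gave 34945 probe sets a single symbol, 932 several and 9160 none, and probe sets with several or none were left out. For 34741 of those with a single symbol the current symbol was looked up through the gene identifier, whether or not it changed. Probe sets whose mean over the 10 arrays was under the 40th percentile of all probe sets, 3.70 log2, were left out, and each gene was represented by its probe set with the highest mean, which left 13523 genes. Groups were taken from the labels. A linear model with the 4 group means was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (prior degrees of freedom 5.34, residual degrees of freedom 6). The 5 contrasts were HCM minus wild type in males, the same in females, the female minus the male HCM change, and female minus male in wild type and in HCM. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes within a contrast. These adjusted p are those of limma, and p-values of the array measures are from exact permutation tests.

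The contrasts, gene lists, rule for naming genes and alternatives were fixed before the data were examined, except where stated. The 38 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with the correlation estimated from the data. For each list the members that passed over all genes and those that passed adjusted over the list alone were counted. The rule for the genes named in each contrast took the 10 genes with the highest and the 10 with the lowest log2 change among those that passed and whose groups of arrays did not overlap, up to 4 members of each list with the smallest p whether or not they passed, and a fixed set of heart, fibrosis, estrogen receptor and sex-linked genes. For the difference between the HCM changes it took 5 and 5, or the 5 highest and 5 lowest moderated statistics where fewer than 5 passed. Symbols that only number a clone or a predicted gene were passed over for naming and stayed in the counts. Members of lists named beyond that rule were chosen after their values were seen.

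The alternatives were no filter or one at the 60th percentile, every probe set tested separately, the mean of a gene's probe sets, leaving out probe sets that can cross-hybridise, quantile normalization of the deposited values again, centring each array on its median, a fit on only the arrays compared, an intensity trend with robust variances, array weights, the replicate number as a fixed or random block, a minimum change of 1.5-fold, fry in place of camera, and leaving out each array in turn. A fit without the 2 female arrays of replicate 1 and the mean HCM change over both sexes were added after the data were seen. Other splits of the arrays were refitted in the same way. The procedure was tested on simulated data drawn from each gene's mean over the 10 arrays and its moderated variance, independently between genes, with 200 changed genes per contrast. In the comparison of HCM males with wild-type males it called 53.7%, 98.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, in females 17.9%, 86.6% and 98.5%, and for the difference between the HCM changes 4.48%, 59.7% and 100%. The simulated male and female arrays had the same variance for a gene. In the data the array weights, lower for noisier arrays, were 0.41 to 0.60 in females and 1.23 to 2.12 in males. The rates for females and for the difference are therefore likely too high. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of every value, and genes near the filter are close to background.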

Results

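RNA from the left ventricles of C57BL/6 mice was measured on 10 Affymetrix Mouse Genome arrays of 45101 probe sets. The mice carried either the wild-type genotype or a genotype labelled HCM, hypertrophic cardiomyopathy, a disease in which the heart muscle thickens. There were 3 arrays of wild-type males, 3 of HCM males, 2 of wild-type females and 2 of HCM females, and the replicates were pools of 2 or 3 animals, all 2 months old. Every animal ate a casein diet with the phytoestrogens genistein and daidzein, plant compounds that bind estrogen receptors, so no array shows what the diet itself does. The comparisons ask which genes differ with the HCM genotype in each sex on this diet, whether that difference depends on sex, and how the sexes differ within each genotype. After the filters 13523 genes were tested, and the number of arrays limits the precision of every value. Changes are log2 ± the standard error of the limma fit, which shares its estimate of a gene's spread over all 10 arrays. The genes named for the size of their change are those in which no array of one group overlapped the other group.

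The 6 male and the 4 female arrays stood apart before any gene was tested. The bacterial dap transcript, a control that a laboratory can add to RNA, is made by no mouse. It read 8.42 ± 0.09 (SD, n = 6) on the male arrays and 3.31 ± 0.14 (SD, n = 4) on the female arrays (exact two-sided permutation p = 0.00476, the smallest that 210 arrangements allow). All 4 female values lay below the filter on low signal, so they are background and the difference is a lower bound. No label says whether the transcript was added to every RNA. The spread of the log2 values on an array averaged 1.97 in males and 1.84 in females. A first principal component with 60.1% of the variance separated the sexes, with mean scores of -21.6 in males and 32.4 in females. The array of female_WT replicate 1 had the highest 18S rRNA signal, 10.8 log2, and a 3' to 5' difference for Gapdh of 1.56 log2, against at most 0.58 on the other arrays. Female_HCM replicate 1 had the highest score on the first component, 53.4. The HCM comparisons stayed within a sex and so within each side of the split in added transcripts. A 3' to 5' difference for actin did move with genotype, at 1.47 to 1.55 log2 on the wild-type and 1.07 to 1.21 on the HCM male arrays, and 1.15 to 1.73 on the wild-type and 0.90 to 1.05 on the HCM female arrays. That for Gapdh overlapped between the genotypes. It was 0.35 to 0.45 log2 on the wild-type and 0.43 to 0.47 on the HCM male arrays. On the female arrays it was 0.43 and 1.56 in wild type and 0.24 and 0.58 in HCM. Each side held arrays of 1 sex only, so the sex comparisons have no value within a side.

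**Figure D1:**
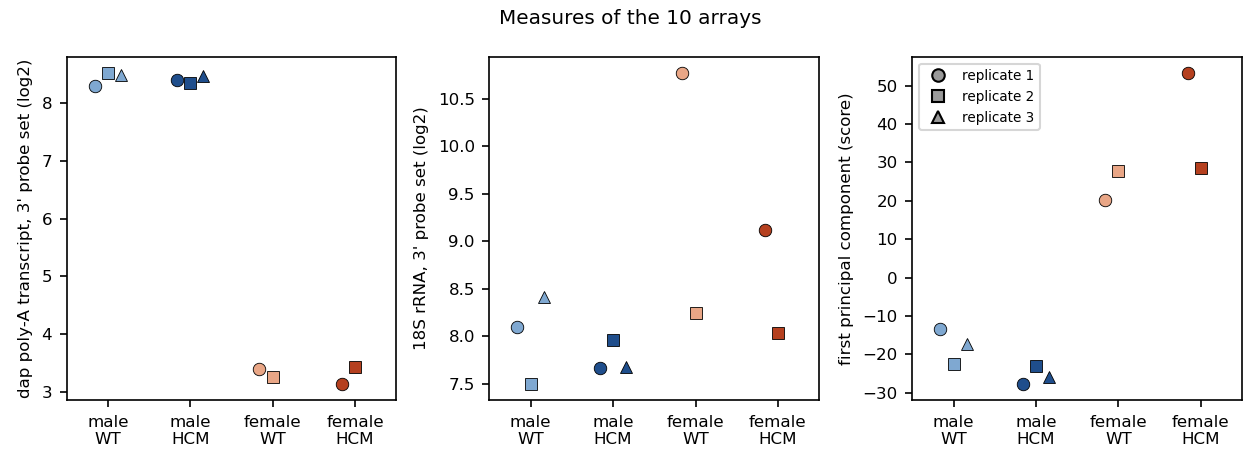
Log2 signal of the added dap poly-A transcript, log2 signal of 18S rRNA and the score on the first principal component for each of the 10 arrays, by group, with marker shapes for the replicate numbers. The dap signal was 8.30 to 8.52 on the male arrays and 3.13 to 3.44 on the female arrays, where it lay below the filter on low signal.

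In HCM males, several genes of the cardiac stress response rose. Myh7, the slow myosin heavy chain that the adult mouse ventricle normally keeps low, rose by 2.84 ± 0.41 log2 (7.15-fold, n = 3 against 3, adjusted p = 0.0159). The natriuretic peptides Nppa and Nppb rose by 2.14 ± 0.35 and 1.30 ± 0.18 log2 (adjusted p = 0.0282 and 0.0147). Rcan1, an inhibitor of the phosphatase calcineurin that is itself induced by calcineurin signalling, rose by 1.85 ± 0.27 log2 (adjusted p = 0.0159). Of the 19 measured genes of the hypertrophy and fetal programme, 6 rose, none fell and 13 did not pass, while 15 rose when adjusted over the list alone. Their median change was 1.15 log2 (camera adjusted p = 5.6e-18, and adjusted p = 0.136 with an estimated correlation). Acta1, the skeletal actin of the fetal heart, was 1.65 log2 higher without passing (adjusted p = 0.0789). The main adult myosin Myh6 was at -0.08 ± 0.09 log2 and the calcium pump Atp2a2 at -0.10 log2, and neither passed (adjusted p = 0.858 and 0.808). Both read 14.1 log2 or more on every array, near the highest signals of 14.6 on the male arrays, which limits what their values can show.

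**Figure D2:**
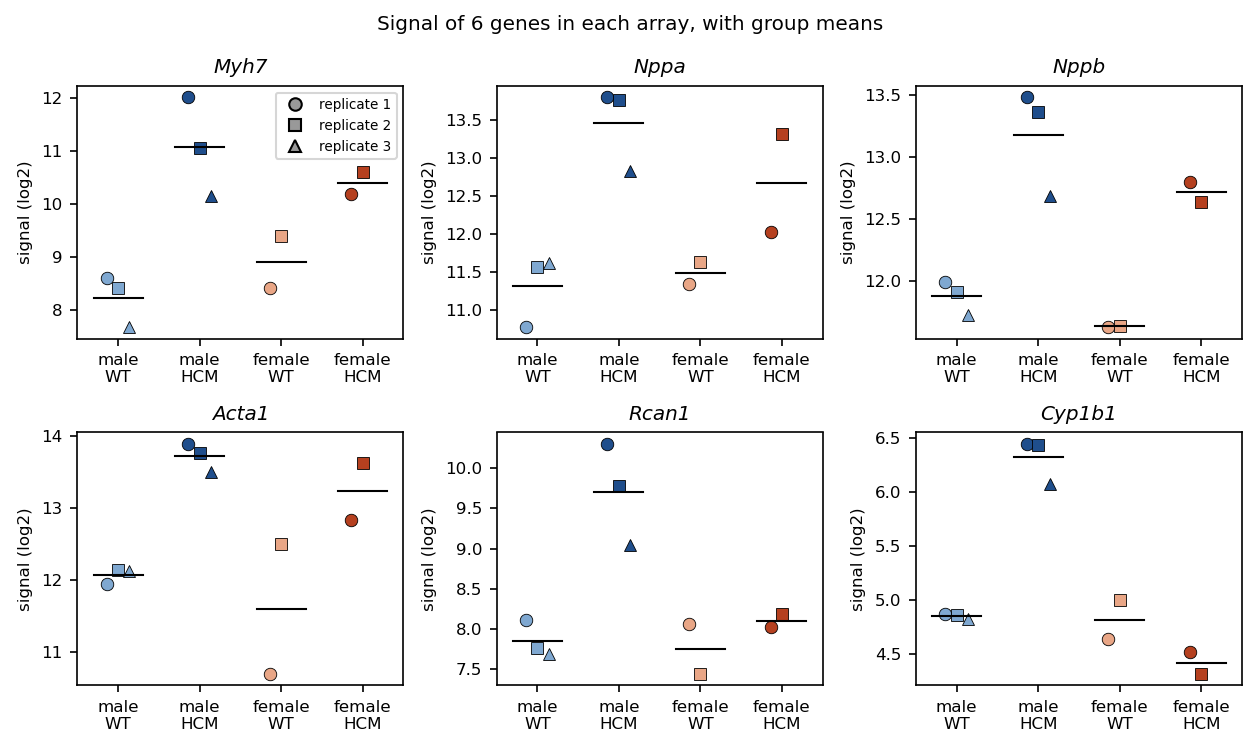
Log2 signal of 6 genes in each array, by group, with a line at the group mean and marker shapes for the replicate numbers. The mean of Myh7 was 8.24 in wild-type and 11.1 in HCM males, and Cyp1b1 was at 6.32 in HCM males against 4.85, 4.82 and 4.42 in the other groups.

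Single genes of the matrix and heat shock lists also rose in HCM males. Cilp, a matrix protein, rose by 2.13 ± 0.21 log2 (adjusted p = 0.00141), and it was the 1 gene of the 34 matrix and fibrosis genes that passed over all genes. Adjusted over the list alone 20 of them rose, and the list had a median of 0.62 log2 (camera adjusted p = 4.3e-19, and adjusted p = 0.136 with an estimated correlation). Its members Col8a1, Tgfb3 and Thbs4 were at 1.61, 0.79 and 1.30 log2 with adjusted p of 0.0509, 0.0570 and 0.0658. Postn, Ccn2 and Timp1, genes of fibrotic tissue, were at 1.24, 1.90 and 2.21 log2, and did not pass (adjusted p = 0.132, 0.190 and 0.353). Among 17 heat shock genes, Hsp90aa1, Hsph1 and Hspb1 rose by 1.06, 1.17 and 1.06 log2, and 10 rose when adjusted over the list alone (list median 0.41, camera adjusted p = 1.7e-11, and adjusted p = 0.136 with an estimated correlation). None of the 16 fibroblast markers passed over all genes, and 6 of them, Mfap4 at 0.88 log2 among them, rose when adjusted over the list alone (camera adjusted p = 2.0e-06, and adjusted p = 0.136 with an estimated correlation).

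Among genes of mitochondrial fuel use 1 passed in HCM males, and most members lay below wild type by small amounts. Of 31 fatty acid oxidation genes, 30 were below wild type. Eci1, an isomerase for unsaturated fatty acids, fell by 0.57 ± 0.10 log2 (adjusted p = 0.0325), and 14 fell when adjusted over the list alone. The list median was -0.29 log2 (camera adjusted p = 8.1e-17, and adjusted p = 0.136 with an estimated correlation). Of 35 oxidative phosphorylation genes 34 were lower, none passing alone, at a median of -0.14 log2 (camera adjusted p = 6.7e-08, and adjusted p = 0.295 with an estimated correlation). The 15 genes of the tricarboxylic acid cycle had a median of -0.18 log2, with 14 below wild type, and 4 of them, Suclg2 and Idh2 among them, fell when adjusted over the list alone (camera adjusted p = 3.0e-06, and adjusted p = 0.136 with an estimated correlation). In the list of ion channels and gap junctions Kcnj3, a potassium channel subunit, fell by 0.89 ± 0.16 log2 (adjusted p = 0.0397) as 1 of 16, with 3 falling when adjusted over the list alone (median -0.24, camera adjusted p = 1.1e-04, and adjusted p = 0.136 with an estimated correlation).

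Further genes with the largest rises in HCM males were Casq1, a calcium store protein of skeletal muscle, at 2.08 ± 0.33 log2 (adjusted p = 0.0264), the lipid carrier Apod at 2.06 ± 0.14 (adjusted p = 0.000172), Lrrcc1 at 1.99, Masp1 at 1.67, the myosin light chain Myl1 at 1.52, and Cyp1b1, an enzyme that oxidizes estrogens, at 1.47 ± 0.14 (adjusted p = 0.00141). Casq1 and Mybpc2, at 1.22 log2, were the 2 of 9 skeletal muscle markers that rose, over all genes as well as over the list alone, with a list median of 0.16 (camera adjusted p = 0.0201, and adjusted p = 0.136 with an estimated correlation). The glucose transporter Slc2a1 rose by 0.99 log2, the receptor kinase Grk5 by 1.01 and the natriuretic peptide clearance receptor Npr3 by 1.35. The largest falls were those of Ces1d at -1.40, Ano10 at -1.29, Shld1 at -1.27, the vessel growth factor Angpt1 at -1.24 ± 0.12 (adjusted p = 0.00141), Cabcoco1 at -1.16 and Cmtm8 at -1.14 log2. Camk2g, a calmodulin kinase gene, fell by 0.96 log2. Among 24 estrogen receptor and estrogen-responsive genes Lifr, a cytokine receptor, fell by 0.86 log2 and 23 did not pass, and adjusted over the list alone 1 rose and 1 fell. The receptor Esr1 was at 0.12 log2 (adjusted p = 0.893), and Esr2 was below the filter. Interferon response genes had a median of 0.27 log2, with 3 of 22 rising when adjusted over the list alone (camera adjusted p = 7.0e-05, and adjusted p = 0.621 with an estimated correlation). The 24 immediate early genes had a median of 0.22 log2 with none passing (camera adjusted p = 0.00979, 0.530 without male_HCM replicate 1, and adjusted p = 0.621 with an estimated correlation).

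In all 71 genes passed in HCM males, 48 higher and 23 lower, with 1439 at an unadjusted p under 0.05 where 676 would be expected by chance. The count depended on which arrays were used, although all 71 kept their sign when any array was left out. It was 28, 12 and 6 without male_WT replicates 1, 2 and 3, and 4, 6 and 126 without male_HCM replicates 1, 2 and 3. It was 153 without either female_HCM array, 217 on the male arrays alone and 592 with array weights. Without male_HCM replicate 2 the skeletal muscle markers had a camera adjusted p of 0.0632. In 5 of the 10 ways to split the 6 male arrays 3 against 3, the labelled one included, 11 or more lists passed, the number that passed for HCM.

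In HCM females the called genes were mostly lower. Arrays of the same group correlated at 0.980 to 0.987 in females and 0.992 to 0.996 in males. The standard errors below rest on the spread shared with the male arrays and can understate that of the female arrays. Mgst1, a membrane glutathione transferase, fell by 1.77 ± 0.29 log2 (n = 2 against 2, adjusted p = 0.0383), and Xpo7, a nuclear transport receptor, by 1.65 ± 0.31 (adjusted p = 0.0456). The cytokine Il15 fell by 1.57 ± 0.19 (adjusted p = 0.0245), Fdft1, an enzyme of cholesterol synthesis, by 1.37 ± 0.18 (adjusted p = 0.0245), and Angpt1 by 1.32 ± 0.15 (adjusted p = 0.0230). Klhdc2, Wnk2, Trp53bp1, Agtpbp1 and Zfp266 fell by 1.24 to 1.30 log2. The genes that rose did so by smaller amounts, with Tpx2, a spindle protein, at 1.01 ± 0.19 log2 (adjusted p = 0.0456), Apom at 0.88, Itgbl1 at 0.87, Spata46 at 0.85, Apc2 at 0.85, Fzd4 at 0.81, Il18bp at 0.80, Slc29a4 at 0.79 and the receptor kinase Erbb2 at 0.78. Srsf10 rose by 0.79 log2 on its probe set with the highest signal and was at -0.084 as the mean of its probe sets.

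Among the gene groups in HCM females, 29 of 31 fatty acid oxidation genes were below wild type. Plin5, a lipid droplet protein, fell by 1.06 ± 0.16 log2 (adjusted p = 0.0383) and 6 fell when adjusted over the list alone. The list median was -0.30 log2 (camera adjusted p = 3.9e-05, 0.0801 without female_WT replicate 2, and adjusted p = 0.659 with an estimated correlation). The 19 hypertrophy genes had a median of 0.15 log2 and a mean of 0.47, with none passing over all genes and 5 rising when adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.659 with an estimated correlation). Nppb was at 1.08 ± 0.22 log2 (adjusted p = 0.0539), Acta1 at 1.64 ± 0.44 (adjusted p = 0.0992), Myh7 at 1.49 ± 0.51 (adjusted p = 0.157) and Nppa at 1.18 ± 0.43 (adjusted p = 0.176), so none of these passed in females. Trdn, a protein of the calcium release unit, fell by 1.02 log2 as 1 of 17 calcium handling genes, over all genes and over the list alone. Canx, a chaperone of the endoplasmic reticulum, fell by 0.84 log2 as 1 of 23 unfolded protein response genes, over all genes and over the list alone, and was at 0.26 on a probe set less open to cross-hybridisation. Matrix genes with a median of 0.10, interferon response genes with a median of 0.16 and skeletal muscle markers with a median of 0.19 log2 each had a camera adjusted p of 0.0479, and adjusted p = 0.696, 0.696 and 0.659 with an estimated correlation. After quantile normalization the medians of the matrix, interferon and hypertrophy genes were 0.25, 0.23 and 0.23 log2, and after centring 0.20, 0.26 and 0.26, while that of the skeletal muscle markers was 0.22 and 0.29 and that of the fatty acid oxidation genes -0.23 and -0.20. With no filter the matrix, interferon and skeletal muscle lists were at an adjusted p of 0.118, 0.0972 and 0.119. Without female_HCM replicate 2 these 3 lists were at 0.816, 0.852 and 0.270, and without female_WT replicate 2 at 0.157, 0.260 and 0.141. Without female_WT replicate 1 the matrix genes and the skeletal muscle markers were both at 0.0699.

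In all 87 genes passed in HCM females, 11 higher and 76 lower, with 2562 at an unadjusted p under 0.05. Scaling moved the split of directions, to 28 higher and 58 lower after quantile normalization and 29 higher and 52 lower after centring each array on its median. Single arrays moved the count far more. It was 1883 without female_HCM replicate 2, 394 without female_WT replicate 2, 1 without female_WT replicate 1 and 0 in limma without female_HCM replicate 1 (1980 at an unadjusted p under 0.05). Without both female replicates 1, a choice made after the data were seen, it was 1. It was 7, 0 and 1 without male_WT replicates 1, 2 and 3 (2266 at an unadjusted p under 0.05 without replicate 2), and 2, 2 and 11 without male_HCM replicates 1, 2 and 3, arrays that enter this comparison only through the shared estimate of the spread. With array weights or on the 4 female arrays alone it was 0 (1072 and 1076 at an unadjusted p under 0.05). All 87 genes kept their sign in each of these 10 fits.

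**Figure D3:**
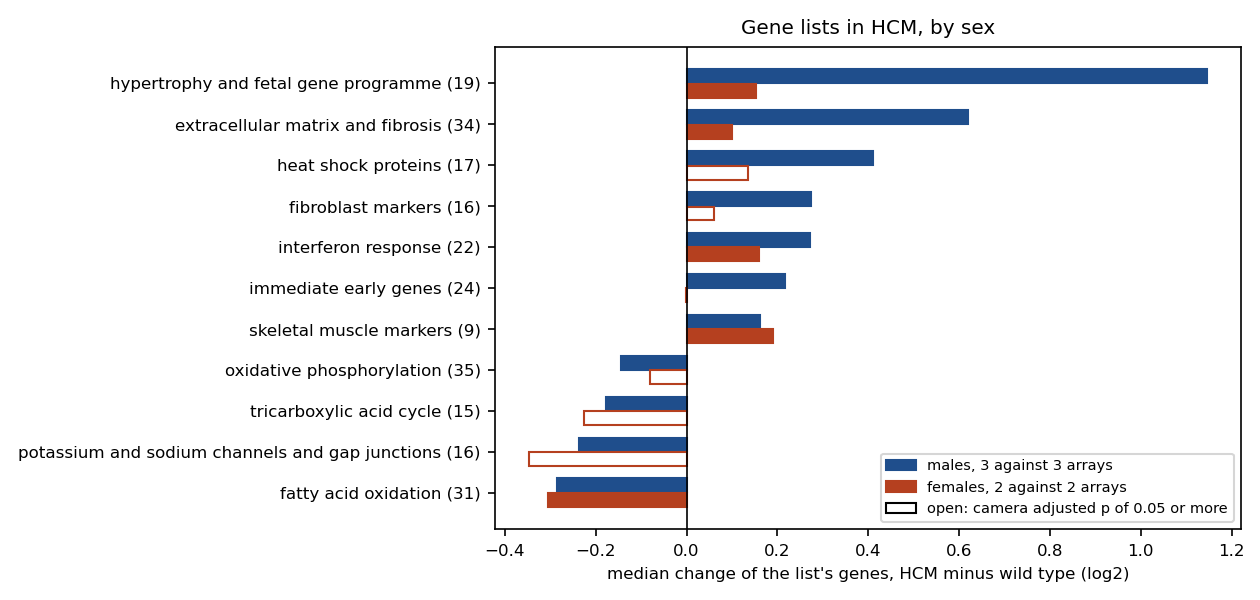
Median log2 change, HCM minus wild type, of the genes of each list that passed camera in either sex, for males and females, with the number of measured genes in brackets and open bars where the adjusted p was 0.05 or more. Fatty acid oxidation genes had medians of -0.29 in males and -0.30 in females, and hypertrophy genes 1.15 and 0.15.

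Between the sexes, the changes in HCM had the same sign in most of the called genes and in 52.5% of all tested genes. Of the 71 genes called in males 58 (81.7%) had the same sign in females, with a median change there of 0.44 log2 in the male direction against 1.01 in males. Picking the genes on the male arrays favours a larger male median, so these medians do not show a smaller change in females. Of the 87 called in females 65 (74.7%) had the same sign in males, and the highest share among other arrangements of the male labels was 78.2%. Itgbl1 rose in both sexes (0.039 genes expected by chance), and Agtpbp1, Dnajc28, Fdft1, Fbp2, Angpt1 and Amy1 fell in both (0.129 expected). Angpt1, the ligand of the endothelial receptor Tek, fell by 1.24 log2 in males and 1.32 in females. The 2 comparisons share no array. Across all tested genes the changes correlated at r = 0.207 and rho = 0.108, and genes are not independent replicates. The share of 81.7% ranged from 63.4% without female_HCM replicate 2 to 92.9% without male_WT replicate 1.

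**Figure D4:**
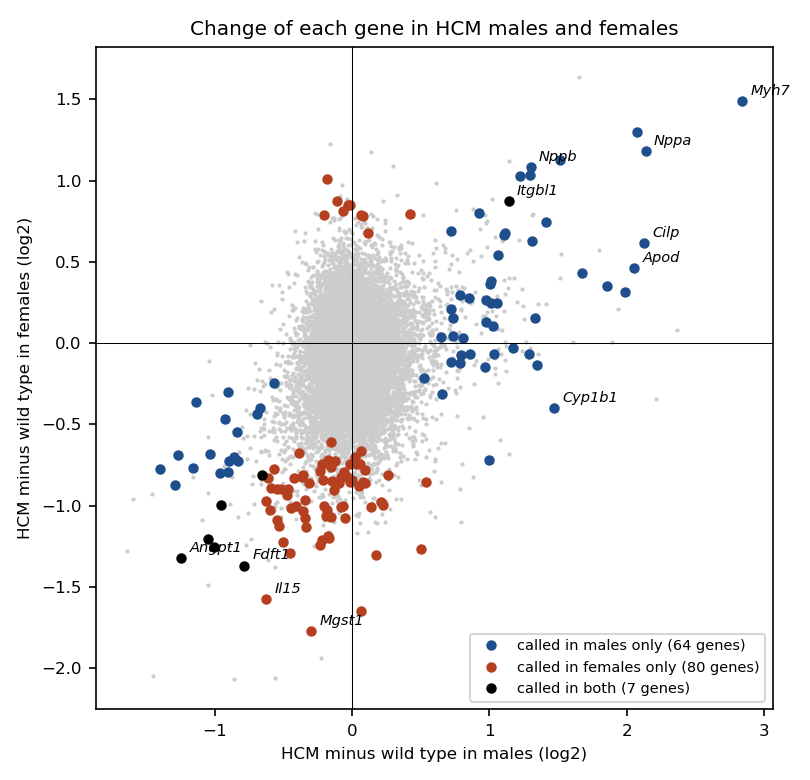
Log2 change in HCM females against the log2 change in HCM males for the 13523 tested genes, with the genes called in males, in females and in both coloured. The 7 genes called in both lie at -0.66 or lower in males or, for Itgbl1, at 1.14.

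The fit also tested whether the HCM change itself differed between the sexes. Cyp1b1 was the 1 gene of 13523 that passed, with a change 1.87 ± 0.21 log2 lower in females than in males (-1.87, adjusted p = 0.0308). Its mean was 4.85 in wild-type and 6.32 in HCM males, and 4.82 in wild-type and 4.42 in HCM females. By moderated statistic, and not by size, the next genes on the lower side were Cntd1 at -1.39, Apod at -1.59, Slc2a1 at -1.71 (adjusted p = 0.0633 for each) and Trp53bp1 at -1.77 log2, and those on the higher side were Slc29a4 at 0.99 (adjusted p = 0.167), Ltk at 0.97, Defa39 at 0.82, Srsf10 at 0.72 and Spata46 at 0.87, none of which passed. Timp1 and Ccn2 had larger differences than Cyp1b1, -2.56 ± 1.35 and -1.89 ± 0.87 log2, and did not pass (adjusted p = 0.428 and 0.369). Matrix and fibrosis genes were lower as a list, 31 of 34 of them, at a median of -0.48 log2 (camera adjusted p = 0.00233, and adjusted p = 0.856 with an estimated correlation). The median was -0.30 after quantile normalization and -0.35 after centring. Cilp, at -1.51 log2, was the 1 member that passed adjusted over the list alone, and none passed over all genes. For Myh7, Nppa, Nppb and Acta1 the differences were -1.35, -0.96, -0.22 and -0.02 log2 (adjusted p = 0.392, 0.459, 0.770 and 0.993), so a different HCM change between the sexes was not shown for them.

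The difference between the sexes had 1838 genes at an unadjusted p under 0.05. Cyp1b1 kept its direction in every fit, from -2.05 to -1.70 log2 with 1 array left out, and its adjusted p ranged from 0.00649 to 0.170. It passed in 3 of these 10 fits, those without male_HCM replicate 3, female_WT replicate 2 or female_HCM replicate 2, in which 5, 7 and 1251 genes passed. In limma without any other single array 0 genes passed, with 1323 to 1506 at an unadjusted p under 0.05, and 0 passed after centring or with array weights (1784 and 1127). The matrix list was at 0.164 without female_WT replicate 2 and 0.191 without female_HCM replicate 1. With the replicate number as a fixed block Cyp1b1 was at -1.87 log2 and did not pass (limma adjusted p = 0.121). Because male and female arrays differed in their added transcripts, the test of the difference also crosses that split.

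Between the sexes in wild type, the label genes separated as the sexes do. Xist, the RNA that silences an X chromosome in females, was 3.95 ± 0.17 log2 higher in females (15.5-fold, adjusted p = 6.3e-07). The Y-linked genes Eif2s3y, Uty and Kdm5d were lower by -5.14, -1.13 and -0.83 log2, all 3 measured members of that list, over all genes and over the list alone (camera adjusted p = 0.00101, and adjusted p = 0.418 with an estimated correlation). Of 22 genes of glucose use 9 were higher in females and none lower, over all genes as well as adjusted over the list alone. They included Pfkl, a phosphofructokinase, at 0.84 ± 0.12 log2 (adjusted p = 0.00187), the kinase Pdk2 at 1.02, the glycogen phosphorylase Pygm at 0.64 and the aldolase Aldoa at 0.41. The list median was 0.26 log2 (camera adjusted p = 0.0213, 0.0576 without male_WT replicate 3, 0.0605 without female_WT replicate 1, 0.170 with the mean of a gene's probe sets, 0.0708 with a fixed replicate block, and adjusted p = 0.418 with an estimated correlation). Calcium handling genes Slc8a1, Trdn and Cacnb2 were lower by -1.83, -0.89 and -0.55 log2, the 3 of 17 that passed over all genes, with 1 higher and 4 lower when adjusted over the list alone and no shift of the list (camera adjusted p = 0.429). Over all tested genes 18.2% passed in this comparison, and the counts of calcium handling genes and of the macrophage markers that follow lie near that share. In macrophages, Mrc1, Laptm5, Ctss and F13a1 are expressed markers, and these 4 of 24 were lower by -1.06, -0.71, -0.81 and -0.62 log2, over all genes and over the list alone (camera adjusted p = 0.150). Of 11 atrial and conduction markers 3 were higher and 1 was lower, with Myh7b at 1.37 and Stard10 at 0.92 log2, and 4 and 1 when adjusted over the list alone (list median 0.66, or 0.85 after quantile normalization, camera adjusted p = 0.0887). Laptm5 was at 0.19 as the mean of its probe sets. Other large differences were Erdr1 at 2.14, Rpl27a at 1.99, Nipsnap2 at 1.83 and Rpn1 at 1.61 log2, and Crim1 at -2.51, Kmt2e at -2.51, Luc7l2 at -2.49, Fyttd1 at -2.23 and Fzd4 at -2.10 log2.

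In all 2465 genes passed between wild-type females and males, 921 higher and 1544 lower in females, of which 1475 differed by at least 1.5-fold. The arrays compared also lie on the 2 sides of the split in the added dap transcript. The higher and lower counts were 1495 and 903 after quantile normalization, and 1392 and 1372 after centring. The total was 949 without male_WT replicate 2, 1410 without male_WT replicate 3 and 1296 without female_WT replicate 2.

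Between HCM females and HCM males, Col8a1, Cilp and Postn of the matrix genes were lower. Col8a1, a short-chain collagen, was at -2.59 ± 0.35 log2, Cilp at -1.63 ± 0.23 and Postn at -1.59 ± 0.35 (adjusted p = 0.000307, 0.000364 and 0.00451). Of 34 matrix genes 13 were lower and 1 was higher, over all genes and over the list alone, at a median of -0.52 log2, and the matrix list did not pass (camera adjusted p = 0.0654). Over all tested genes 41.6% passed here in either direction. The counts of matrix genes and of the macrophage markers and atrial and conduction markers below lie near that share. The median of the matrix list was -0.13 log2 after quantile normalization and -0.32 after centring. Among 17 heat shock genes 10 were lower and 1 was higher, over all genes and over the list alone, with Hsp90aa1 at -1.29 and Chordc1 at -1.52 log2 (list median -0.61, or -0.29 after quantile normalization and -0.41 after centring, camera adjusted p = 0.0528). Macrophage markers had 9 of 24 lower and 1 higher, over all genes and over the list alone, with Ptprc at -1.90 and Laptm5 at -1.60 log2 (list median -0.45, or -0.17 after quantile normalization and -0.26 after centring, camera adjusted p = 0.0555), and Laptm5 was at 0.19 on a probe set less open to cross-hybridisation. The atrial and conduction markers Myh7b, Stard10 and Shox2 were higher by 1.31, 1.07 and 0.53 log2, among 4 of 11 that passed over all genes and 3 over the list alone (list median 0.53, or 0.78 after quantile normalization, camera adjusted p = 0.0528). Slc2a1 was at -2.15 and Cyp1b1 at -1.90 log2, genes whose level rose in HCM males. The label genes Xist and Eif2s3y were at 4.01 and -4.67 log2. Further large differences were Aqp11 at 2.19, Asb6 at 2.14, Tpx2 at 1.98 and Psapl1 at 1.95 log2, and Tex10 at -2.81, Abtb2 at -2.79, Trp53bp1 at -2.72 and Cpxm2 at -2.66 log2.

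In HCM 5620 genes passed between the sexes, 2072 higher and 3548 lower in females, and 3548 of the 5620 differed by at least 1.5-fold. With array weights 3654 passed and without female_HCM replicate 1 3651 passed. The higher and lower counts were 2894 and 2241 after quantile normalization and 4101 and 2582 after centring, which moved the median of all genes from -0.05 to 0.15 log2. The sex differences of the 2 genotypes, which share no array, correlated across genes at r = 0.804, with genes not being independent replicates. They shared 614 higher genes (141 expected by chance) and 1402 lower genes (405 expected), and 2 genes passed in opposite directions. Both comparisons use 1 estimate of each gene's spread, so the expected numbers are likely too low. These arrays too were split by the added dap transcript.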

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

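All tests weighed in this part were chosen only after the result was seen, except the split of the 6 male arrays for the count of genes in HCM males. Cyp1b1 was marked because its HCM change differed between the sexes by -1.87 log2 in a test of the difference itself. The extracellular matrix and fibrosis list was marked for the same reason, with a camera adjusted p of 0.00233, and 0.856 with an estimated correlation. The added poly-A transcript dap was marked because a signal outside the gene measurements separated the groups, 5.11 log2 higher on the male than on the female arrays. The female values lay below the filter on low signal, so this size is a lower bound.

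Large numbers of genes differed between the female and male arrays, 2465 in wild type and 5620 in HCM. Unequal signal distributions as the whole source are argued against by the 2398 genes that passed in wild type after every array got one distribution. Of these, 1650 were among the 2465 and the others were not, and the higher and lower counts moved from 921 and 1544 to 1495 and 903. Giving every array one distribution does not undo a separate normalization of the male and female arrays, on which the labels are silent. Separate preparation of the male and female arrays goes with the dap signal, which left a gap of 4.86 log2 between the lowest male and the highest female array. The largest range within a sex was 0.31. The female values lay below the filter on low signal, so the gap is a lower bound and the female range is one of background. That the transcript was absent from the female RNA is not excluded. Sex of the animals also stays open, since the female minus male changes of the 2 genotypes correlated across genes at 0.804, a value that either source would give. Because the dap level followed sex on all 10 arrays and no label records a preparation, the shares of these 2 sources cannot be told apart. Nor can the share of a separate normalization of the sexes, if there was one.

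Most genes called in HCM females were lower, 76 of 87, and their number moved with single arrays. In 83.9% of them female_HCM replicate 1 lay farther from wild type than replicate 2, past the 75% set for it after the result was seen. The genes were called on these same arrays and no share over all genes was taken, so this share does not decide whether that array was a source of calls. The fall of the count without that array does not single it out either, as the count fell to between 0 and 11 without a male array. The count rose without female_HCM replicate 2, which goes with replicate 1 standing apart, but it also rose without female_WT replicate 2. Each of these 2 fits left a lone array in a group. On the first component female_HCM replicate 1 scored 53.4 and replicate 2 scored 28.5. Angpt1 and Il15 stayed at -1.25 and -1.39 log2 or lower with any array left out. Degraded RNA in female_WT replicate 1, the array with the 18S signal of 10.8, stays open too. That array lay farther from HCM than its partner in 71.3% of the called genes, short of the 75% set for it after the result was seen. The same limit holds for this share. For the HCM genotype, 74.7% of the called genes had the same sign in the male arrays, but the highest of the other arrangements of the male labels reached 78.2%. The HCM changes at 2 probe sets of a gene correlated across 5776 genes, which are not independent replicates, at 0.115 in females against 0.481 to 0.604 in males cut to 2 against 2 arrays, the female value was 0.240 and 0.023 without female_WT replicates 1 and 2 and 0.167 and 0.099 without female_HCM replicates 1 and 2, and the genotype and the state of single arrays cannot be told apart for the called genes.

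The rise of Cyp1b1 in HCM males and not in HCM females was weighed as the third pattern. Smaller changes on the female arrays stay open, since the upper 95% limit of the female change, -0.036 log2 against a male rise of 1.47, comes from the arrays on which the gene was picked for this difference and decides nothing. With 1 array left out the difference nearest to 0 was -1.70 log2. The gene was picked on these same arrays for a difference large against their spread. That value could therefore hardly fall far, and it does not decide whether a single array was the source. The limma adjusted p ran from 0.00649 to 0.170 without 1 of the male arrays. Sex of the animals stays open too, since the added dap transcript also followed sex on all arrays and the probe set of Cyp1b1 with the next highest mean, below the filter, gave a difference of 0.17 log2 that is near background. Sex, smaller changes on the female arrays and a separate preparation, which no label records, cannot be told apart for this gene.

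For the 71 genes called in HCM males, 10 splits of the 6 arrays are too few for a share under 0.05. The labelled split called 71 genes and the highest of the other splits 0, so 1 of the 10 splits gave as many. For the 11 lists that passed in HCM males, 5 of the 10 splits passed as many, and the highest other split passed 17, and these splits too are too few for a share under 0.05. The hypertrophy, matrix, heat shock, fatty acid oxidation, oxidative phosphorylation, tricarboxylic acid cycle, ion channel, fibroblast and skeletal muscle lists each had their lowest camera p in the labelled split. The interferon response had a p as low in 3 of the 10 splits and the immediate early genes in 5. All these lists were picked because they passed in the labelled split. The lowest unadjusted camera p in another split was 1.8e-14 for the hypertrophy, 1.2e-14 for the matrix and 4.3e-09 for the heat shock list. It was 2.2e-07 for fatty acid oxidation, 5.9e-06 for oxidative phosphorylation and 5.3e-04 for the tricarboxylic acid cycle. For the ion channel, fibroblast and skeletal muscle lists it was 1.7e-04, 0.00142 and 0.0553.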

How the results depend on the processing

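The alternatives here were planned except the fit without the 2 female arrays of replicate 1 and the mean HCM change over both sexes, which were chosen only after the data were seen. Where a value changed, the cause was not tested, apart from changes that follow from fewer arrays or more probe sets being tested. A lone array left in a group is assumed to vary like the other groups. With each array left out in turn, the genes passing ranged from 4 to 153 in HCM males, 0 to 1883 in HCM females, 0 to 1251 for the difference between the HCM changes, 949 to 3461 between the sexes in wild type and 3651 to 6184 in HCM, and the share of male-called genes with the same sign in females from 63.4% to 92.9%. The lists passing ranged from 1 to 7 in HCM females, 0 to 6 for the difference, 1 to 3 between the sexes in wild type and 0 to 10 in HCM, and from 10 to 15 in HCM males. The interferon list in HCM females ranged from an adjusted p of 6.7e-07 to 0.852, the latter without female_HCM replicate 2 and lower in place of higher.

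Tested separately, 150 probe sets passed in HCM females, 0 for the difference (2977 at an unadjusted p under 0.05), 4343 between the sexes in wild type and 8903 in HCM. With the mean of a gene's probe sets 32 genes passed in HCM females and the shared sign was 91.4%. It was 91.9% after quantile normalization. After centring it was 90.7%, and 0 genes passed for the difference in limma (1784 unadjusted). On only the arrays compared 217 passed in HCM males and 0 in HCM females (1076 unadjusted). With an intensity trend and robust variances 165 passed in HCM females. Array weights gave 592 in HCM males, 0 in HCM females, 0 for the difference and 3654 between the sexes in HCM. A minimum of 1.5-fold left 1475 and 3548 genes between the sexes in wild type and HCM. Without female_WT 1 and female_HCM 1 together 217 passed in HCM males, 1 in HCM females and 2 for the difference.

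The replicate numbers showed no pairing, with 2 of 13 same-number pairs correlated over 0.1 and 3 under -0.1 after group means were removed, and a consensus correlation of -0.074. With the replicate block fixed 3 genes passed in HCM females, 0 for the difference (1550 unadjusted) and 1502 between the sexes in wild type, against 52 in HCM males. With the replicate block random 45 passed in HCM males and 5 in HCM females, with a shared sign of 91.1%. Lists passing with the replicate block fixed were 2 in HCM females, 3 for the difference, 1 between the sexes in wild type and 5 in HCM.

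With an estimated correlation 0 lists passed in HCM males, HCM females, the difference and the sexes in wild type. By fry, which does not compare a list with other genes, 0 passed for the difference, 6 between the sexes in wild type and 19 in HCM. With no filter 4 lists passed for the difference and 5 between the sexes in HCM, with the filter at the 60th percentile 2, 1 between the sexes in wild type and 4 in HCM, and with the mean of a gene's probe sets 2, 1 and 2. In HCM males the immediate early genes and skeletal muscle markers had an adjusted p of 0.0525 and 0.0771 at the 60th percentile filter, and by fry the interferon, immediate early and fibroblast lists had 0.482, 0.489 and 0.0588. In HCM females the hypertrophy, matrix, interferon and skeletal muscle lists had 0.322, 0.758, 0.721 and 0.0917 by fry, and the matrix list for the difference had 0.376.

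Among single genes, some took the opposite sign in a few settings. Of those below, Ddx3x in wild type and Lonp2, Prkaca and Cnp in HCM also passed with that opposite sign (limma adjusted p = 0.0260, 0.0244, 0.0274 and 0.0115). With the mean of a gene's probe sets Srsf10 in HCM females was at -0.084 log2, and between the sexes Kcnip2 was at -0.17, Laptm5 at 0.19 and Ddx3x at -0.71 in wild type, and Ogdh at -0.075 and Mmrn2 at 0.021 in HCM. Without probe sets that can cross-hybridise Canx in HCM females was at 0.26, between the sexes in wild type Laptm5 was at 0.14, Ighm at -0.054, Hspe1 at 0.085 and Cnp at 0.11, and in HCM Ufsp1 was at -0.44, Lonp2 at -0.40, Myom2 at 0.073, Hadh at 0.053, Laptm5 at 0.19, Canx at 0.17, Hspe1 at 0.052, Prkaca at 0.34, Cnp at 0.54, Ager at -0.086 and Eif2s3x at -0.031. For the named genes in HCM males the alternatives kept direction and call in 3379 cases, lost the call in 175, gained one in 90 and changed the sign of a change that passed in neither in 10, with none reversed. In HCM females these were 3349, 278, 70 and 54, with 2 reversed. Genes near the filter of 3.70 log2 lie close to background, and their changes are bounded by it.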

Other observations

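The tests in this part, among them the mean HCM change over both sexes and its splits, were chosen only after the data were seen. With the male and female HCM changes averaged, 215 genes passed, 57 higher and 158 lower, and 213 of them had the same sign in both sexes, which selection on the mean of the 2 changes favours (52.5% over all tested genes). Among the higher ones were the brain natriuretic peptide Nppb at 1.19 ± 0.14 log2 (adjusted p = 0.00513), Myh7 at 2.16 ± 0.33 (adjusted p = 0.0108), the matrix genes Cilp at 1.37 and Svep1 at 0.88, the collagen hydroxylase P4ha1 at 1.08, the cytokine receptor Tnfrsf12a at 1.16, and the muscle genes Casq1, Myl1 and Mybpc2 at 1.69, 1.32 and 1.13. Among the lower ones were Angpt1 at -1.28 ± 0.09 (adjusted p = 0.000329), the cholesterol synthesis enzyme Fdft1 at -1.08, Il15 at -1.10, the muscle fructose bisphosphatase Fbp2 at -0.97, the kinase genes Camk2g and Wnk2 at -0.88 and -0.87, the peroxisomal transporter Abcd3 at -0.69, the NAD synthesis genes Naprt and Nampt at -0.83 and -0.72, and Trdn at -0.73. These genes were chosen after their values were seen. The count was 141, 86 and 77 without male_WT replicates 1, 2 and 3, 75 and 66 without male_HCM replicates 1 and 2, 51 without female_WT replicate 1, 420 without female_WT replicate 2 and 1277 without female_HCM replicate 2.

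Splits of the arrays within each sex give 60 arrangements, enough for a share under 0.05. The labelled one called 215 genes and the highest of the others called 5, so 1 of 60 gave as many, a share under 0.05. That share is the smallest that 60 arrangements allow. The count was chosen after the data were seen, so chance is not excluded for it. The 3' to 5' difference for actin, though not that for Gapdh, also separated the genotypes within each sex. These arrangements therefore do not part the genotype from the state of the RNA. The correlation across genes, which are not independent replicates, of the HCM changes in males and in females, 0.207, was reached by 4 of the 60 arrangements with a highest other value of 0.287, so chance is not excluded for it. Mean changes of whole lists over both sexes were farthest from 0 in the labelled arrangement for the hypertrophy list at 0.77 log2, the fatty acid oxidation list at -0.33, the ion channel list at -0.38, the oxidative phosphorylation list at -0.13, the tricarboxylic acid cycle list at -0.21, the heat shock list at 0.38, the growth factor signalling list at -0.12 and the skeletal muscle markers at 0.38. Each has an exact p of 0.0167, the smallest that 60 arrangements can give, and an adjusted p of 0.0792 over the 38 lists, so none passed the correction.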
